A study of Mus musculus with 6 samples.

How the data were processed

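Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts open DNA and adds sequencing adapters to it, in retinas of C57BL/6 mouse embryos at E14.5 (embryonic day). Per the labels, 3 libraries came from Atoh7 +/+ animals (called wild type here) and 3 from animals homozygous for a mutated Atoh7 shadow enhancer (called SE/SE). Each library was made from the retinal pair of an individual animal, so the 3 libraries of a genotype are biological replicates. Per the labels' protocols, about 100000 cells were transposed and the equivalent of 50000 cells was amplified. The wild-type libraries had 17, 18 and 19 PCR cycles and the SE/SE libraries 15, 16 and 16, with no label that ties a cycle number to a library, so amplification and genotype cannot be separated.

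The submitters' processing notes name cutadapt, BWA, Genrich 0.5, bedtools 2.27.0, limma and the mouse build GRCm38 (mm10), without the role or order of each. The deposited files are 8 peak lists in narrowPeak form, 1 for each of the 6 libraries and 2 joint lists that the authors named for a genotype. How reads were trimmed, shifted for the Tn5 cut, freed of duplicates or filtered is not given in the sources used here. Each deposited peak has a signal value, a score and −log10 p-values. In all 8 lists the lowest deposited signal value was 20, and the deposited score equalled 1000 times the signal value over the peak's width, to within 1 and with a cap at 1000, for 100% of the peaks. The authors' deposited signal value is thus tied to peak width, and no scaling between libraries is given in the sources used here, so it was used only to describe and rank peaks inside one list, as was the deposited −log10 p. No read counts were analysed here: the depth of each library is unknown, and the number of peaks and the bases they cover are the only depth-related values.

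Positions were taken on chromosomes 1 to 19, X and Y and are printed counting from 1. The peaks of the 6 libraries were merged into consensus regions wherever they shared 1 bp or more, and a library had a region if one of its peaks overlapped it. A region with a peak in all 3 libraries of one genotype and in 0 of the other 3 was called genotype-specific. The count of such regions was set against the count from a model with a region effect and a library effect and no genotype term, fitted by conditional maximum likelihood, and against the other ways to split the 6 libraries into 3 and 3, which make 10 splits with the real one. A region is assigned to a protein-coding gene of the RefSeq table for GRCm38.p6, the build of the files. That table gives gene starts and ends without strand or exons. The planned distance to a transcription start site was therefore replaced by the distance to the nearer end of a gene, up to 100 kb, and the planned split of genes into exons and introns by a single class inside genes. A start site that lies inside the longest annotated gene span is missed by this measure.

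Group differences of values per library were tested by exact two-sided permutation over all 20 assignments, which cannot give a p under 0.1 with 3 against 3. Before the data were examined, 13 gene lists for cell types and processes were fixed: retinal ganglion cell, retinal progenitor, neurogenic transition, photoreceptor and cone, amacrine and horizontal, bipolar and Muller glia, pigment epithelium and ciliary margin, lens, endothelial, microglia and blood, mesenchyme and optic stalk, cell cycle, and housekeeping promoters. They have 305 entries, all matched by symbol, and 4 genes (Ebf3, Isl1, Prox1 and Sall3) stand in 2 lists. For each list, the mean of SE/SE minus wild-type libraries with a peak was taken over its regions with a peak in 1 to 5 libraries. It was ranked among 10000 random lists matched on the number of such regions per gene, with Benjamini-Hochberg adjustment over the 13 lists. Regions and genes are not replicates, so these p-values describe these 6 libraries.

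The rule for named genes, also fixed before the data were examined, took Atoh7, the genes of up to 10 regions per genotype that were genotype-specific and had a peak in their own joint list only (ranked by joint-list signal value), and up to 4 genes per list with the most genotype-specific regions, ties going to the highest joint-list signal value. The part on joint lists gave only Atoh7, since 0 of the SE/SE-specific regions lacked a joint wild-type peak. Not every gene that this rule takes is reported here. The 15 fixed motifs were not analysed here, since no genome sequence was used. Alternatives covered the overlap, the region definition, stricter lists, lists of equal length, the gene distance, the chromosomes and each library left out in turn.

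The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were tested on simulated data. With 200 regions per genotype planted among 43570 simulated regions, the model for genotype-specific regions returned 200 wild-type-specific regions against 0.03 expected and 6190 SE/SE-specific regions against 5981 expected. With no planted region, 6127 SE/SE-specific regions stood against 6101 expected. The other simulated regions were drawn from a region effect and a library effect, as in the model. No graded gain over many regions in SE/SE was simulated, so this check does not cover such a gain. Of 100 simulated lists of 30 genes with a shift of 1 library per region, the list test gave an unadjusted p below 0.05 in 100, and in 4 of 100 lists without a shift. That shift is large against the SDs of 0.071 to 0.216 of the random lists used below. Smaller shifts were not simulated, so the power to find them is unknown.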

Results

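Open chromatin of the mouse retina at E14.5, an embryonic day when retinal ganglion cells are being born, was profiled in 3 wild-type and 3 SE/SE libraries. SE/SE animals are homozygous for a mutated shadow enhancer of Atoh7, which encodes a basic helix-loop-helix transcription factor needed for the formation of retinal ganglion cells. A shadow enhancer is an additional element that drives a gene in a pattern overlapping that of its primary enhancer. The comparison of genotypes asks which accessible regions differ when the shadow enhancer is mutated. The wild-type libraries had 31340, 34797 and 27873 peaks and the SE/SE libraries 39115, 42722 and 44242. The read depth behind these lists is unknown.

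At Atoh7 (gene ID 53404, chromosome 10, 63099785 to 63101280 in GRCm38), SE/SE libraries lacked peaks at one place outside the gene. All 3 wild-type libraries had peaks at 63089257 to 63089634 and at 63090131 to 63090667, which end 10150 and 9117 bp before the gene's lower-coordinate end, and none of the 3 SE/SE libraries had either. In wild type 1, 2 and 3 the first region's peaks had signal values of 407, 427 and 268, at percentiles 62.6, 62.6 and 52.3 of their own lists. Those of the second region had 209, 272 and 98.6, at percentiles 47.8, 53.3 and 30.6. Both regions lie in one joint wild-type peak, 63089099 to 63090927, with an authors' signal value of 8034 (rank 5831 of 104991 in that list), and the joint SE/SE list had no peak there. This place therefore separates the libraries as their genotype labels do.

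Of the consensus regions within 100 kb of Atoh7, only these 2 had a peak in wild-type libraries alone. Regions at the gene itself, 63099535 to 63099837 and 63099998 to 63100606, had a peak in all 6 libraries. A region at 63098174 to 63098595, 1189 bp from the gene, had a peak in wild type 2 and in all 3 SE/SE libraries, and in both joint lists. The 3 remaining regions, near Hnrnph3, Pbld2 and Pbld1, had a peak in 6 of 6 libraries. Of the 8 consensus regions in this window, 5 were thus shared by all libraries, 2 were wild-type-specific, 1 was partly shared and 0 were SE/SE-specific.

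**Figure D1:**
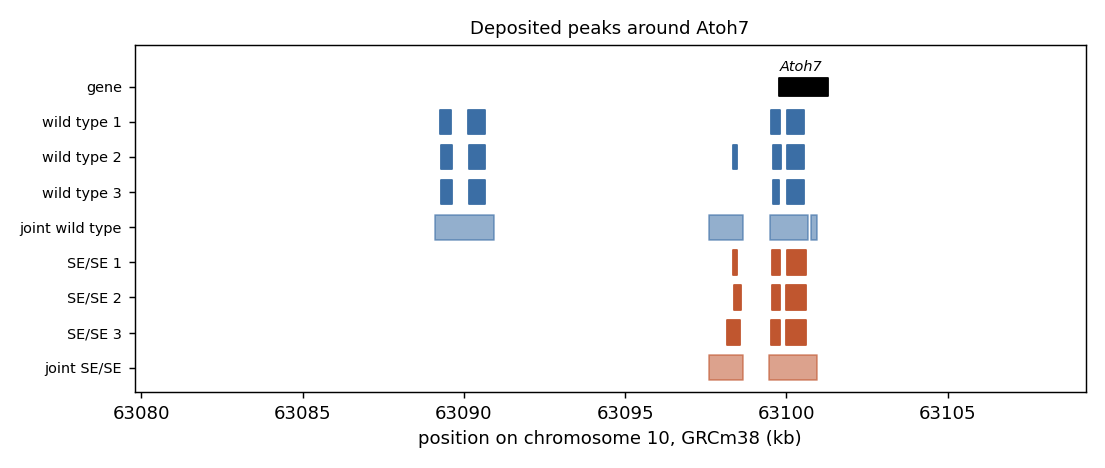
Deposited peaks around Atoh7, by position on chromosome 10 in kb (GRCm38); each bar is a peak, blue for wild type and orange for SE/SE, with the joint list of each genotype in a lighter shade and the gene in black. The 2 regions from 63089257 to 63090667 have peaks in the 3 wild-type libraries and in no SE/SE library, while the regions at the gene have peaks in all 6.

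Peaks more than 1 kb from a gene end, inside or outside genes, were more numerous in SE/SE libraries. Peaks more than 1 kb from a gene end numbered 28503 ± 2520 per library in SE/SE (SD, n = 3) and 18391 ± 3158 in wild type (SD, n = 3), a ratio of 1.55 with an exact permutation p = 0.1. Peaks within 1 kb of a gene end numbered 13523 ± 114 in SE/SE and 12946 ± 321 in wild type, a ratio of 1.04 (exact permutation p = 0.1). Over all peaks, SE/SE libraries had 42026 ± 2633 and wild-type libraries 31337 ± 3462, and the bases covered were 19.0 ± 1.36 Mb and 13.9 ± 1.5 Mb (exact permutation p = 0.1 for each). In each of these measures the 3 libraries of one genotype lay wholly above the other 3, which gives the smallest p that 3 against 3 allows. PCR cycle numbers also separate the genotypes, with fewer cycles in SE/SE.

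**Figure D2:**
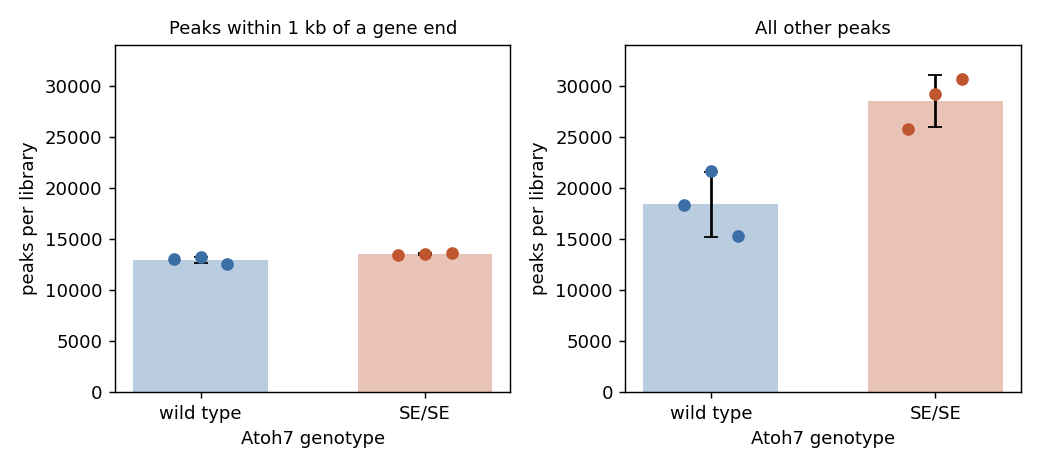
Peaks per library within 1 kb of a gene end (left) and elsewhere (right) for wild type and SE/SE; points are libraries, bars are means and error bars are SDs over 3 libraries. Peaks near gene ends averaged 12946 and 13523, and other peaks 18391 and 28503.

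Region by region, wild-type-specific accessibility was rare. Of 46780 consensus regions, 24370 had a peak in all 6 libraries. Among the 24436 regions with a peak in all 3 wild-type libraries, 99.7% also had one in all 3 SE/SE libraries. Only 15 regions were wild-type-specific, against 0.011 expected from library effects alone, and the 2 at Atoh7 were the only ones of these without a peak in the joint SE/SE list. The model also missed other patterns. Regions in 1 wild-type library alone numbered 293 against 118 expected, and those in 2 alone 43 against 1.17. Regions in 1 wild-type and 2 SE/SE libraries numbered 924 against 1269. The excess over 0.011 therefore does not establish a genotype effect at each of the 15 regions. The SE/SE-specific regions numbered 3849, against 3531 expected from library effects, a ratio of 1.09. The library effects of all 3 SE/SE libraries lay above those of all 3 wild-type libraries, so the model absorbs a general gain in SE/SE. This ratio therefore does not exclude such a gain. All 3849 SE/SE-specific regions overlapped a peak of the joint wild-type list. These SE/SE-specific regions were mostly away from gene ends: 9.90% lay within 1 kb of one, against 45.6% of the regions with a peak in all 6 libraries. Of all 46780 regions 29.4% (13755) lay there, and 11122 of these 13755 had a peak in all 6 libraries. Of the 15 wild-type-specific regions, 1 (6.67%) did. A low share is thus not shown to be particular to SE/SE-specific regions. The peaks of SE/SE-specific regions ranked low in their own lists, at a median percentile of 18.9 by signal value.

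These counts moved with the lists. With the same number of peaks from each library, 98 wild-type-specific and 433 SE/SE-specific regions were counted, against 17.2 and 189 expected, and the 2 regions at Atoh7 were again among the first. Without wild type 2 the counts were 36 and 7019, without SE/SE 1 they were 27 and 6764, and without wild type 3 the wild-type-specific regions numbered 30.

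**Figure D3:**
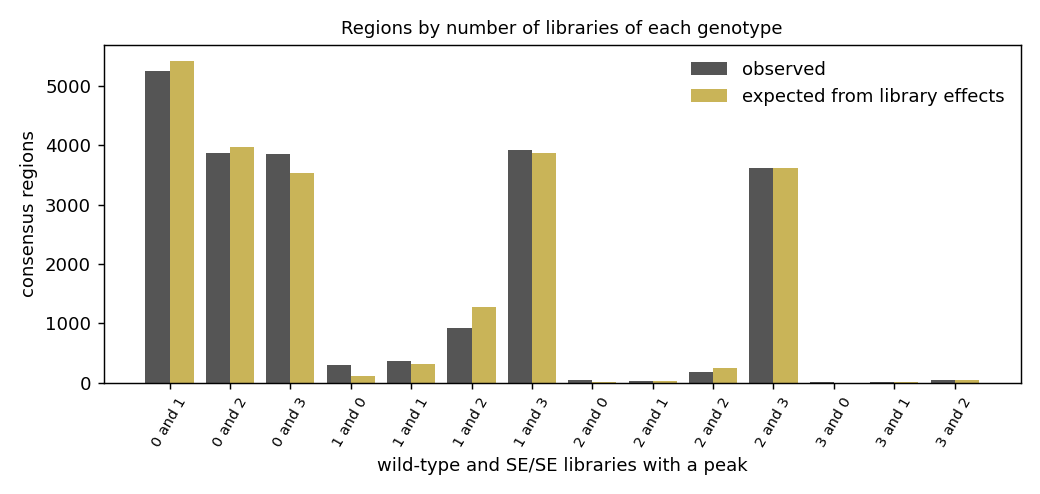
Consensus regions by the number of wild-type and SE/SE libraries with a peak (horizontal axis), counted (grey) or given by library effects without a genotype term (yellow); the 24370 regions with a peak in all 6 libraries are left out. Regions in 0 wild-type and 3 SE/SE libraries numbered 3849 against 3531 expected. The library effects separate the genotypes completely and so absorb a general gain in SE/SE.

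In the joint lists, the Atoh7 peak stood out among peaks found in wild type only. The joint wild-type list held 104991 peaks, of which 98397 (93.7%) overlapped a joint SE/SE peak and 6594 did not. Among those 6594, the Atoh7 peak had the highest signal value, 8034, followed by a peak at 10690591 to 10691144 on chromosome 6 with 1635, which has no protein-coding gene end within 100 kb. The Atoh7 peak was also the only one of them with a peak in all 3 wild-type libraries, while 6588 had a peak in none. The joint SE/SE list held 120772 peaks, of which 26521 (22.0%) had no overlap in the joint wild-type list, and 0 of these 26521 had a peak in any SE/SE library. With no replicates of a joint list, these counts have no test.

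Retinal ganglion cell genes with a peak near a gene end in all wild-type libraries also had one in all SE/SE libraries. This is not particular to the list: of all consensus regions with a peak in 3 wild-type libraries, 99.7% also had one in 3 SE/SE libraries. A peak within 1 kb of a gene end was found for 37.3 ± 2.31 of the 51 listed genes in SE/SE libraries (SD, n = 3) and for 32.7 ± 2.52 in wild-type libraries (exact permutation p = 0.1; adjusted p = 0.26 over 13 lists). In all, 5 of the 13 lists had this p, the smallest that 3 against 3 allows, each with more genes in SE/SE; the other 4 are given below. Of the 51 listed genes, 29 had such a peak in 6 of 6 libraries and 11 in none. Pou4f2, Isl1 and Pou4f1, transcription factor genes of retinal ganglion cells, had such a peak in 6 of 6 libraries, Eomes in 2 wild-type and 3 SE/SE libraries, and Thy1 and Isl2 in 0 of 6 although in both joint lists. Pou4f2, Isl1, Pou4f1, Eomes, Thy1 and Isl2 are all outside the rule for named genes. Of the 299 regions assigned to this list, 24 were SE/SE-specific and 0 wild-type-specific. The microtubule gene Mapt had 3 SE/SE-specific regions, the one with the highest joint signal value at 104232250 to 104232587 on chromosome 11, inside the gene and with its midpoint 3010 bp from a gene end. The vesicular glutamate transporter gene Slc17a6 had 2, and Rbpms was among the genes with 1. The mean difference of SE/SE minus wild-type libraries over the list's 170 partly shared regions was 1.6, against 1.64 ± 0.071 (SD) in matched random lists (gene permutation p = 0.53, adjusted p = 0.91).

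Most genes of the progenitor and neurogenic states had a peak near a gene end in all libraries of both genotypes. All 21 neurogenic transition genes, among them the proneural gene Neurog2, had a peak near a gene end in 6 of 6 libraries, as did 29 of 34 progenitor genes. Beside the 2 wild-type-specific regions of Atoh7, the neurogenic list had 13 SE/SE-specific regions, 2 each at Neurog2, the Notch ligand gene Dll4, Onecut1 and Sstr2, the last of these outside the rule for named genes and chosen after its values were seen. That of Onecut1 with the highest joint signal value lay outside the gene at 74860530 to 74861007 on chromosome 9, with its midpoint 1152 bp from a gene end. The progenitor list had 23, of which Meis1 had 4, Pax6 3, Meis2 3 and Nfib 2, and that of Pax6 with the highest joint signal value lay at 105681405 to 105681743 on chromosome 2, inside the gene. Pax6 had 28 regions in all, 16 of them with a peak in 6 of 6 libraries. The mean differences were 1.63 for the neurogenic and 1.62 for the progenitor list, against 1.63 ± 0.140 and 1.61 ± 0.105 (SD) in matched random lists (adjusted p = 1.0 for each).

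In single libraries, gene ends of photoreceptor genes were often without a peak in both genotypes. Of the 24 photoreceptor genes, 7 had a peak near a gene end in 6 of 6 libraries and 15 in none, while the joint lists had one for 14 genes in wild type and 18 in SE/SE. Otx2 had none in 6 of 6 libraries although in both joint lists. This list had 5 SE/SE-specific regions, 3 at Otx2 and 1 each at Prdm1 and Rorb. Of the 22 amacrine and horizontal genes, 15 had such a peak in all libraries, and the list had 14 SE/SE-specific regions, 2 each at Barhl2, Slc32a1, Prdm13 and Tfap2b. The 16 bipolar and Muller glia genes had a peak near a gene end in 10.7 ± 0.577 cases in SE/SE and 9.0 ± 0 in wild type (SD, n = 3, exact permutation p = 0.1, adjusted p = 0.26). This list had 4 SE/SE-specific regions, 1 each at Glul, Grm6, Slc1a3 and Grik1, and Grm6 had a peak near its end in 3 SE/SE and 0 wild-type libraries. The mean differences of 1.71, 1.75 and 1.47 for these lists stood against 1.64 ± 0.161, 1.63 ± 0.129 and 1.63 ± 0.155 (SD) in random lists (adjusted p = 0.91 for each).

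For markers of cells outside the neural retina, no mean difference passed an adjusted p of 0.05. The counts of genes with a peak near a gene end could not pass it, since 3 against 3 gives no p under 0.1. A peak near a gene end was found for 7.33 ± 0.577 of 14 pigment epithelium genes in SE/SE and 5.0 ± 0 in wild type, for 5.33 ± 0.577 and 2.67 ± 1.15 of 14 endothelial genes, and for 9.67 ± 1.53 and 6.33 ± 0.577 of 17 mesenchyme genes (SD, n = 3, exact permutation p = 0.1 and adjusted p = 0.26 for each). The pigment epithelium list had 6 SE/SE-specific regions, 3 at Mitf and 1 each at Wfdc1, Gpr143 and Ttr, and its mean difference of 1.88 had the lowest unadjusted p of the 13 lists (random lists 1.64 ± 0.177 (SD), gene permutation p = 0.15, adjusted p = 0.91). Wfdc1 and Gpr143, and Flt1 in the endothelial list, had a peak near a gene end in 3 SE/SE and 0 wild-type libraries, as did 188 of all 21887 protein-coding genes, against 0 with the opposite pattern. The lens list had 5 SE/SE-specific regions, 2 of them at Cryaa and 1 each at Prox1, Bfsp2 and Cryba4, and 1 wild-type-specific region, also at Cryaa. The endothelial list had 6, with 2 each at Kdr and Flt1 and 1 each at Esam and Egfl7. The microglia and blood list had 6, with 2 each at Runx1 and Ptprc and 1 each at C1qb and Cx3cr1, and the mesenchyme list had 6, with 2 each at Twist1 and Prrx1 and 1 each at Foxc1 and Pdgfrb. Mean differences were 1.61 for lens, 1.77 for endothelial, 1.84 for microglia and blood and 1.63 for mesenchyme genes, with adjusted p-values of 1.0, 0.91, 0.91 and 1.0.

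Cell cycle and housekeeping genes made up the remaining lists. A peak near a gene end was present in all 6 libraries for 28 of 29 cell cycle genes and 26 of 28 housekeeping genes, with the same number in each library. These counts could hardly rise further, so they are no baseline for the higher counts of other lists in SE/SE. The cell cycle list had 3 SE/SE-specific regions, 2 at Cdkn1c and 1 at Rrm2, and the housekeeping list 5, 2 at Pgk1 and 1 each at Actb, Rab7 and Sdha. Their mean differences, 1.75 and 1.81, stood against 1.64 ± 0.197 and 1.63 ± 0.216 (SD) in random lists (adjusted p = 0.91 for each). Over the 13 lists, 0 passed an adjusted p of 0.05 for the mean difference and 0 had an unadjusted p below it. The number of list genes with an SE/SE-specific region departed from random lists in 0 lists, and that with a wild-type-specific region in 0 lists after adjustment and in 1, lens, before it (1 gene, Cryaa, gene permutation p = 0.017, adjusted p = 0.23).

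**Figure D4:**
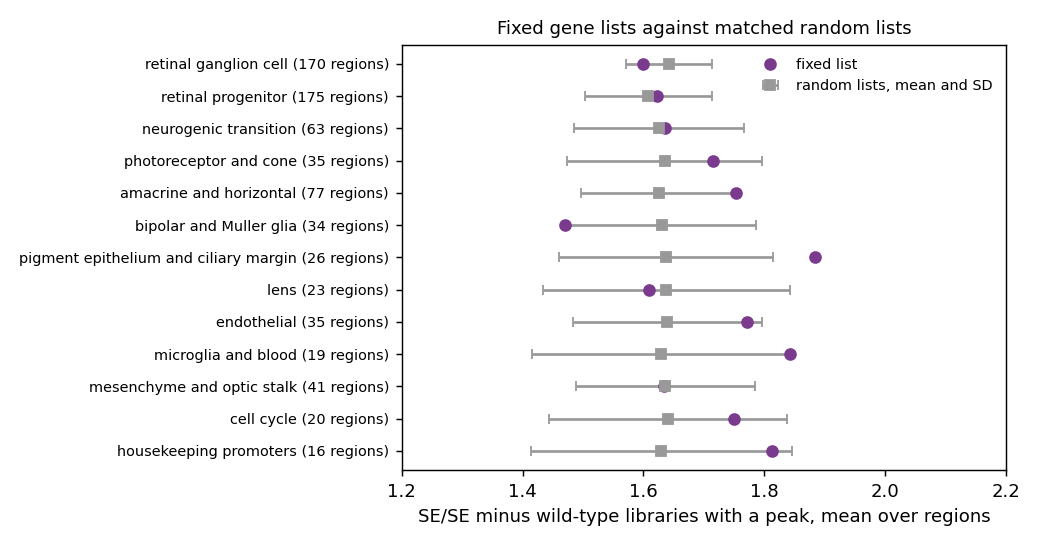
Mean over each list's partly shared regions of SE/SE minus wild-type libraries with a peak (horizontal axis, in libraries), for the 13 fixed lists (purple) and for 10000 matched random lists (grey, mean and SD). The pigment epithelium list, at 1.88 against 1.64 ± 0.177, lies furthest above its random lists, and no list passes the adjusted test.

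A larger share of wild-type peaks lay near gene ends. Within 1 kb of a gene end were 41.6 ± 3.61% of the wild-type peaks (SD, n = 3) and 32.3 ± 1.80% of the SE/SE peaks (exact permutation p = 0.1). Peaks inside genes made up 31.4 ± 1.57% in wild type and 35.6 ± 0.846% in SE/SE, and peaks outside genes 27.1 ± 2.04% and 32.1 ± 0.951%. With the same number of peaks from each library, the difference near gene ends was -2.22 percentage points instead of -9.32.

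On average, libraries of one genotype shared more of their covered bases than libraries of different genotypes. The Jaccard index, the shared bases over all bases covered by a pair, averaged 0.829 within and 0.716 between genotypes, a difference of 0.113 that 1 of the 10 splits reached (exact permutation p = 0.1). Wild type 2 with SE/SE 1, at 0.823, exceeded wild type 1 with 2, at 0.810, and wild type 2 with 3, at 0.778. No pair was nearly identical, the highest index being 0.871. With the same number of peaks from each library, the index averaged 0.848 within and 0.770 between genotypes. That difference, 0.0776, was reached by 1 of the 10 splits (exact permutation p = 0.1). By the share of the shorter list's peaks with an overlap, the difference was -0.021 and its direction turned.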

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

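All alternatives were chosen before the data were examined, except those named here as added. Of 252 alternative values, 201 kept direction and side of the threshold or stayed within 1.5 times the count. The 169 values for single gene lists all stayed short of the adjusted threshold, but 31 of them changed sign. Every count of gene lists past the adjusted threshold stayed at 0, also with differences relative to regions in as many libraries, with regions inside a gene assigned to it, and with wild type 2 and SE/SE 1 both left out (all added). Both wild-type-specific regions at Atoh7 remained under equal list lengths.

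The sign changes concern the difference of a list from random lists, whose cause was not tested. With gene ends within 50 kb it was 0.0259 for lens and 0.0511 for mesenchyme genes, and within 1000 kb 0.102 and 0.0180. With equal list lengths it was -0.134 for progenitor, 0.752 for bipolar and Muller glia, -0.161 for pigment epithelium, 0.0361 for lens, -0.107 for microglia and blood, 0.427 for mesenchyme and -0.609 for cell cycle genes. With unmatched random lists it was -0.00663 for progenitor and 0.00536 for mesenchyme genes. Leaving out 1 library gave -0.0301 to 0.0681 for progenitor, -0.0454 to 0.0924 for neurogenic, -0.240 to 0.134 for lens, -0.0449 to 0.115 for mesenchyme and -0.0800 to 0.00199 for retinal ganglion cell genes. Among the added settings it was -0.0291 for neurogenic and 0.0633 for mesenchyme genes relative to regions in as many libraries, -0.0204 for progenitor and -0.0552 for neurogenic genes with regions inside a gene assigned to it, and 0.00422 for retinal ganglion cell, -0.00484 for neurogenic and 0.00592 for mesenchyme genes with wild type 2 and SE/SE 1 both left out.

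Wild-type-specific regions, 15 in the main setting, numbered 133 with summit windows, 4 in the upper 50% of each list by p, 98 with equal list lengths, 58 with at least 2 of 3 libraries and 49 with wild type 2 and SE/SE 1 both left out (added). Leaving out 1 library gave 16 to 36. SE/SE-specific regions, 3849 in the main setting, numbered 1912 in the upper 50%, 433 with equal list lengths, 7724 with at least 2 of 3 libraries and 10494 with the same 2 libraries left out (added). Leaving out 1 library gave 3958 to 7019. A class of at least 2 of 3 libraries admits more regions by construction; for the other settings the cause was not tested. The planned 50% overlap rule excludes no peak, since a peak always lies inside its region; with peaks required to cover 50% of the region (added), 15 and 4718 regions were counted.

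Peaks of the joint wild-type list alone numbered 19280 with 50% overlap of both peaks, 1197 in the upper 50% and 10194 with equal list lengths, and those of the joint SE/SE list 9715 in the upper 50% and 14708 with equal lengths; the cause was not tested. The overlap within minus between genotypes was -0.021 by the share of the shorter list (exact permutation p = 1.0); that measure ignores the extra peaks of the longer list.

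The replicate numbers in the titles are not said to pair animals. With labels exchanged only within these numbers (a replicate block), the difference of 10690 peaks had an exact p = 0.25, the smallest that 8 assignments give, so the block cannot pass a threshold. Of the 6 libraries, 2 overlapped most with the library of their own number in the other genotype. Motif tests with their alternatives, and the split of genes into exons and introns, were not run. Without read counts, weak regions near the caller's threshold cannot be told from absent ones in a single library.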

Other observations

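The tests named as chosen afterwards in each paragraph were set after the result was seen; genes named in this part were likewise chosen after their values were seen. The peaks found only in the joint SE/SE list included 1 near Egr1, an immediate-early transcription factor gene, at 34865098 to 34866442 on chromosome 18 with the highest signal value among them, 1233. Others were 50958 bp from an end of Megf10 (860) and 264 bp from an end of Lhx4, a LIM homeobox gene (851, at 155751370 to 155751995 on chromosome 1). None of these had a peak in any single SE/SE library. Among the 13 wild-type-specific regions away from Atoh7, all 13 overlapped a peak of the joint SE/SE list. The one that overlapped the joint wild-type peak with the highest signal value, 18368, lay at 58223130 to 58223454 on chromosome 10, its midpoint 889 bp from an end of LOC100504180; in the single wild-type libraries its values were 51.8, 20.7 and 23.3, where the lowest deposited value is 20. The region near Cyp8b1, at 121930328 to 121931432 on chromosome 9, overlapped a joint peak with 9931 and had 174, 242 and 524 in the single libraries, and that near Snd1 2226 with 29.5, 109 and 249.

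The missing peak next to Atoh7 was weighed against technical losses, with both tests set before their results were seen, except that the second region was added afterwards. If a weak peak had dropped below the threshold, equally strong regions should be lost too. Among 11387 other regions with at least the signal value of the region at 63089257 to 63089634 in each wild-type library, and 15169 with that of the region at 63090131 to 63090667, 0 (0%) lacked a peak in all 3 SE/SE libraries, which argues against a weak peak lost below the threshold. If a linked segment of another strain surrounded Atoh7, peaks of one joint list alone should be frequent within 5 Mb. Their frequency there was 15.2% against 14.7% elsewhere, a ratio of 1.04 (Fisher's exact test, p = 0.63). Of such peaks, 6588 of 6594 in wild type and 26521 of 26521 in SE/SE had no peak in any library of their genotype. Their median signal values were 41.6 and 63.7, against 427 and 764 for shared peaks. Most are thus weak calls from lists without replicates, so this test cannot decide on a linked segment. Per the labels, SE/SE animals have a mutated Atoh7 shadow enhancer. That this mutation accounts for the missing peak stays an untested hypothesis, as do other causes not weighed here. Peak lists cannot tell absent sequence from closed chromatin.

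The excess of regions in SE/SE libraries was weighed with tests chosen afterwards. Whether these regions are closed in wild type stays open: the joint wild-type list had a peak at 100% of them, but also at 99.98% of the regions found in 1 SE/SE library only, so this measure is saturated. Whether libraries differ only in how many weak regions pass the peak caller stays open too. The peaks of SE/SE-specific regions had a median percentile rank of 18.9 by signal value in their own lists, so most were weak calls there. Library effects alone gave 91.8% of the SE/SE-specific count (75.9% with summit windows, 43.6% with equal list lengths). But these effects separate the genotypes completely and so absorb a general gain in SE/SE, and a graded gain at weak sites would also give low ranks. A graded gain at weak sites in SE/SE and the fewer PCR cycles in SE/SE libraries (at least 1 cycle fewer than any wild-type library) cannot be told apart, since cycle numbers follow genotype. The real split gave 3864 genotype-specific regions and the highest of the other splits 561. Library effects alone gave 3531 and 723 for these 2 splits, so this gap does not by itself show a genotype effect. With the same number of peaks from each library, the real split gave 531 and the highest of the other splits 156. Of the 10 splits of the full lists, 1 reached the real value, and 10 splits are too few for a share under 0.05.

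Wild type 2 and SE/SE 1 lacked peaks that the other 4 libraries had at Eif2s3y, Uty and Ddx3y on chromosome Y, and each had 1 peak in the first 50 Mb of Y against 7 to 9 in the others, although SE/SE 1 had 37 on Y in all against 10 in wild type 2 and 29 to 45 in the others. A candidate explanation is that these 2 embryos were female. The test set beforehand, a peak within 1 kb of an end of Xist, found it in 0 of these 2 libraries and in 0 of the other 4, so it did not come out as predicted. That window ended short of the nearest peaks: a region 1.12 kb from the end of Xist, at 103482017 to 103482116 on chromosome X, had a peak in wild type 2 alone, the next, 1.35 kb away at 103481647 to 103481883, had one in these 2 libraries and in neither joint list, and a 2.5 kb window, chosen afterwards, found a peak in 2 of these 2 and 0 of the other 4. A region inside Xist, 103477608 to 103477776, had a peak in wild type 2 but also in all 3 SE/SE libraries, and the sex of the embryos stays open.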
